A study of Drosophila melanogaster with 8 samples.

How the data were processed

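The libraries were made from total RNA of dissected discs of 50 to 60 wandering larvae per genotype raised at 25 °C, extracted with a spin-column kit, and each of the 8 groups had 1 library. Counts per gene were deposited by the authors as a single table with 1 column per library and FlyBase gene identifiers. Per the submitters' processing notes, reads were aligned with TopHat2 and counted with HTSeq. The versions, the genome build, the annotation, the strand setting and the rule for overlapping genes are not given in the sources used here, so that reads of antisense or overlapping genes cannot be assigned with certainty. Reads that align to several places are tallied apart from the genes, so that counts of near-identical gene copies are too low or uncertain. The table ends in 5 tally rows, which were left out. In them, reads in no gene made up 3.41 to 7.33% of a library's counted and tallied reads, reads that fit more than 1 gene 1.46 to 1.83%, and reads aligned to several places 14.8 to 27.8%. No column was left unused.

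The table held 15348 genes. Gene names and coordinates came from a BDGP6 annotation, joined by identifier. 14639 identifiers (95.4%) had a name there and 709 did not, which held 9.00 to 9.81% of a library's counts. Of 347 entries in the gene lists 327 were matched, and 20 were not, so that a list speaks for its matched members only. Assigned counts ranged from 17152279 to 21027972 per library, so that 1 count was worth 0.0476 to 0.0583 CPM and 3 counts, taken as the floor, 0.143 to 0.175 CPM. The 20 genes with the highest counts held 8.95 to 10.2% of each library.

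Counts were scaled with edgeR 4.0.16 in R 4.3.3 by the trimmed mean of M values (TMM), and log2 CPM were computed with a prior count of 2. Genes with at least 1 CPM in at least 1 library were considered, 10029 in all. Each comparison was the difference between 2 libraries. A gene was called when it was at least 4-fold apart on that log2 scale with at least 5 CPM in the higher library. A fold given for a single gene is the ratio of normalized CPM without the prior count, with an exact conditional binomial (Clopper-Pearson) 95% interval, and levels have exact Poisson intervals. Where 1 library had 0 counts, the fold was computed against 3 counts in that library and is given as at least that size. Intervals and floors compare the 2 libraries and not the conditions, since reads without molecular identifiers are not independent molecules and there was no replicate.

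The groups of genes were 26 lists. They covered perturbed genes, JNK and AP-1, JAK/STAT, Hippo and Yorkie, Ras/MAPK response, stress transcription factors, retinal determination, photoreceptor differentiation, antenna, wing, matrix and basement membrane, cell cycle, ecdysone response, apoptosis, polarity and adhesion, glycolysis, antimicrobial peptides, heat shock, Turandot and dosage compensation, and markers of hemocytes, fat body, muscle, glia, neurons, and trachea with salivary gland. The antenna list holds antennal and leg appendage patterning genes. Some genes stand in more than 1 list, such as Antp in the antenna and wing lists. The stress transcription factor list shares kay, Jra, Atf3 and Ets21C with the JNK and AP-1 list. It shares chinmo and Stat92E with the JAK/STAT list. For each list the median log2 fold of its considered members was set against 10000 random lists of the same size matched on mean expression in 10 bins, and the band given runs from the 2.5 to the 97.5 percentile. The band describes these libraries and is not a test. Members at least 2-fold higher or lower on the log2 scale with the prior count were counted. Medians of lists with a member at 0 counts were computed again with that member at its bound. Of 29 such medians 9 moved by more than 0.1, and 2 entered their band.

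The genes named are the perturbed genes, for each comparison the 10 with the largest folds each way among called genes with at least 20 CPM and a name, list members past 4-fold, and at most 4 examples per list, the largest in each direction. The lists, the thresholds, this rule, the comparisons and the alternatives below, other than those said to be added later, were fixed before the data were examined. Names outside the rule are marked where they stand.

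Pairs of comparisons were also set side by side where they had no library in common, which removes the link that a shared control makes. Pearson and Spearman correlations were taken over 7628 genes, and shared calls were set beside the number that independent lists would share. The scrib wing discs had no wing control, and no gene of the wing list was at least 2-fold higher there than in control, so that tissue and genotype cannot be told apart. Their levels are given without a comparison, except for list medians over control that check the label. A model with additive effects of the 3 genetic changes over the eye-antennal libraries was not fitted.

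The calling step, the intervals and the random lists were tested on simulated counts for the early tumour over control with 15348 genes. All 100 genes simulated as 8-fold higher were called, none simulated at 3-fold and no unchanged gene was called, and 95.4% of the intervals held the true fold. Both simulated libraries had counting error alone, and the changed genes had a mean of at least 20 CPM, so that these outcomes were largely set by the simulation. It held no variation between animals, dissections or libraries and gives no rate of false calls between conditions. On 9128 genes, 2.5% of 200 unchanged lists lay outside the band. The alternatives were DESeq2 1.42.0 size factors, total counts, upper-quartile scaling, a 2-fold threshold, a level filter of 1 CPM or none, a prior count of 0.5, and leaving out the 20 genes with the highest counts. After seeing the data, counts were also taken without 157 genes that were higher in the control alone and without 271 genes that were at least 4-fold higher in scrib BskDN than in BskDN with at least 5 CPM in scrib BskDN. Further computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.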

Results

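RNA was sequenced from imaginal discs of wandering Drosophila melanogaster larvae of the last instar, the epithelial sheets that form adult head and wing structures. There were 8 groups with 1 library each. By their labels, 7 libraries came from eye-antennal discs and 1 from wing discs. The eye-antennal discs were mosaic: the FLP recombinase, driven in the eye, made clones of cells that lost the Gal80 repressor, so that Gal4 switched on GFP and any transgene in them. The control clones carried no transgene. RasV12 clones expressed an always-active form of the GTPase Ras85D. BskDN clones expressed a dominant-negative form of Basket (bsk), the fly Jun N-terminal kinase (JNK). The scrib BskDN clones lacked scribble (scrib), an apico-basal polarity gene, and expressed BskDN. The RasV12 scrib clones form a malignant tumour model and were taken as an early and a late library, and a further library, RasV12 scrib BskDN, had JNK blocked in that genotype. By the labels, larvae were collected at the wandering stage. This was 5 days after egg laying in control and RasV12, and 6 days in scrib BskDN, RasV12 scrib BskDN and the scrib wing discs. It was 7 days in the early tumour, and 11 days in BskDN and the late tumour. Ecdysone response genes differed between the libraries, as given below, so that an equal stage is not shown.

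The table assigned 18508386 counts to genes in control, 19996678 in RasV12, 19695958 in BskDN, 20032861 in scrib BskDN, 21027972 in RasV12 scrib BskDN, 20566656 in the early tumour, 19835809 in the late tumour and 17152279 in the scrib wing discs. Between 9016 and 9777 genes had at least 10 counts. Values are normalized CPM, the counts of a gene scaled to the library's size and composition. Intervals after folds are exact 95% intervals that cover counting error alone. No group had a replicate, so no difference below was checked against the spread between replicates, and no p-value is given across genes. Called genes were at least 4-fold apart with at least 5 CPM in the higher library, among 10029 genes considered. Coordinates are those of the BDGP6 annotation, joined by gene identifier, because the build used for the counts is not given in the sources used here.

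The genes that the genotypes act on came first, as a check of the labels. Ras85D (FBgn0003205, 3R:9510561-9513067) was at 253 CPM in control (95% interval 246 to 261), 272 CPM in BskDN, 252 CPM in scrib BskDN and 284 CPM in the scrib wing discs, the 4 libraries without RasV12. It was higher in the libraries with the transgene, at 464 CPM in RasV12, 426 CPM in RasV12 scrib BskDN, 655 CPM in the early tumour and 1181 CPM in the late tumour (1166 to 1196), or 4.66-fold over control. The bsk gene (FBgn0000229, 2L:10247502-10250501) was at 99.0 CPM in control (94.6 to 104) and between 92.4 and 109 CPM in the other 4 libraries without BskDN. With BskDN it was at 749 CPM in BskDN alone, 1607 CPM in scrib BskDN and 1891 CPM in RasV12 scrib BskDN, folds of 7.57, 16.2 and 19.1 over control. Both genes went with the labels. The scrib gene (FBgn0263289, 3R:26536350-26604051) lay between 363 and 510 CPM in all 8 libraries, which does not check the label, since the loss of scrib function need not lower its RNA. The same list held 3 pigmentation genes that the stocks carry as markers. The w gene lay between 140 and 273 CPM in the eye-antennal libraries and at 7.01 CPM in the scrib wing discs, and y lay between 10.4 and 21.6 CPM in 6 eye-antennal libraries, at 73.9 CPM in the late tumour and at 0.242 CPM in the scrib wing discs. The third marker gene, e, was at 7.63 CPM in control, 0.298 CPM in RasV12 and 35.4 CPM in scrib BskDN. The median log2 fold of these 6 perturbed and marker genes was within the band of random lists in 5 of the 8 comparisons, for example 0.30 in the early tumour over control, and above it in scrib BskDN over control (0.76), the late over the early tumour (0.45) and the early tumour over RasV12 (0.40).

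None of the 13 genes of the wing list was at least 2-fold higher in the scrib wing discs than in control, and 1, Antp, was lower, so that the values did not go with the tissue label. The wing gene vg was at 2.18 CPM there and 1.45 CPM in control, nub at 3.63 and 5.37 CPM, and Antp at 0.121 and 11.98 CPM. The medians of the wing list (-0.05) and the antenna list (-0.11) over control were within their bands, while those of the retinal determination (-1.60) and photoreceptor (-1.77) lists were below theirs, with eya at 27.2 against 250 CPM and gl at 7.80 against 162 CPM. The protocol that the submitters give for this library, the same text as for the others, speaks of eye-antennal discs. The genes given here were chosen after their values were seen, and the tissue stays open.

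**Figure D1:**
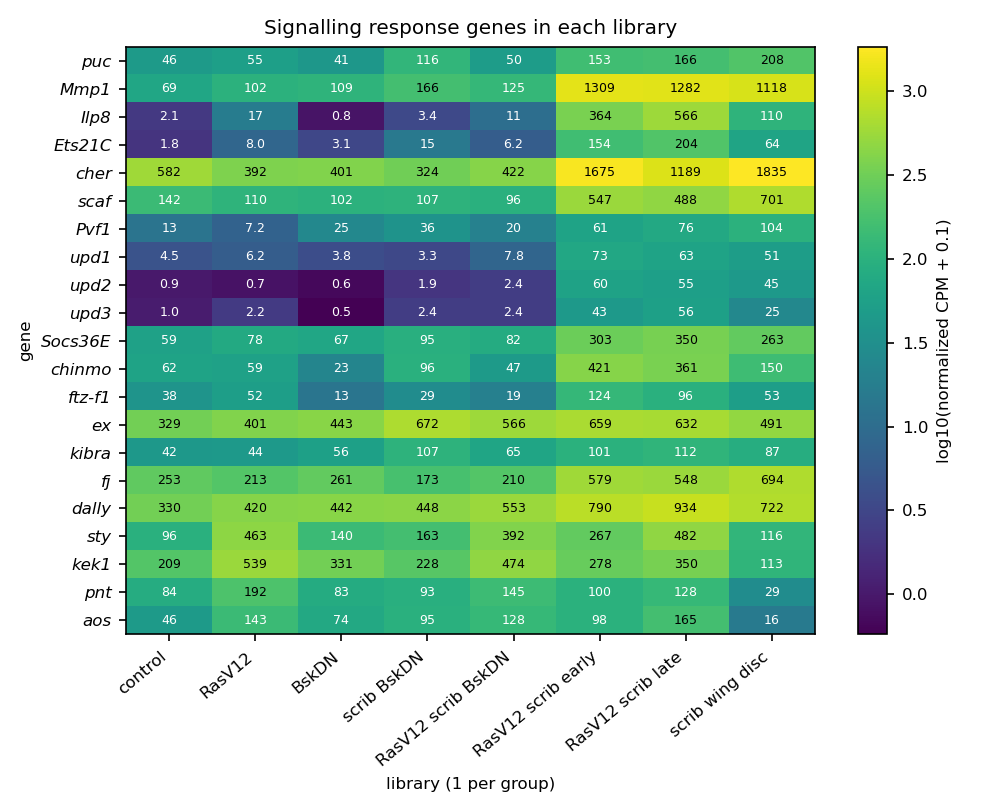
Normalized CPM of 21 signalling genes (vertical axis) in the 8 libraries (horizontal axis), 1 library per column, with the CPM printed in each cell and the color on a log10 scale of CPM plus 0.1. Mmp1 was at 1309 CPM in the early tumour and 1282 CPM in the late tumour, against 68.6 CPM in control and 125 CPM in RasV12 scrib BskDN.

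The comparison of RasV12 with control addressed what active Ras does alone. EGFR and Ras/MAPK feedback genes were higher in the RasV12 library. Sprouty (sty, FBgn0014388, 3L:3401153-3424935), a feedback inhibitor of the pathway, was 4.84-fold higher, at 463 against 95.7 CPM (4.60 to 5.09). The antagonist edl was 3.11-fold (2.72 to 3.57), the secreted EGFR inhibitor aos 3.10-fold (2.87 to 3.34) and kek1 2.58-fold higher (2.48 to 2.67). Of the 12 genes of this list, 7 were at least 2-fold higher and none lower, with a median log2 fold of 1.10 against a band of -0.08 to 0.17 for matched random lists. In the JNK and AP-1 list the relaxin-like peptide gene Ilp8 was 8.04-fold (5.76 to 11.5) and the Ets factor gene Ets21C 4.41-fold higher (3.03 to 6.58), at 16.8 and 8.04 CPM, and mol was 2.84-fold lower (2.35 to 3.45). These were the only members of 15 past 2-fold, and the list median was 0.19. Of the 10 genes of the antenna list 2 were higher and 2 lower, with a median of 0.12 within its band: al was 3.61-fold and Lim1 3.13-fold higher, while Antp was 9.28-fold lower (6.17 to 14.5). The median of the retinal determination list was -0.24, with dac 2.11-fold lower, while that of the photoreceptor list was 0.43.

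Of the genes called in this comparison, 93 were higher in RasV12 and 328 lower. Most of the higher genes with the largest folds encode salivary gland glue proteins: Sgs5 (3R:17595362-17596112) was 62.9-fold (50.9 to 78.8) and Sgs3 30.6-fold higher (26.6 to 35.5). The fat body gene Fbp1 was 5.41-fold higher (5.15 to 5.70). In the trachea and salivary gland list 6 of 11 genes, each of them an Sgs gene, were at least 2-fold higher and 2 were lower (median 4.41). Of the fat body markers 6 of 9 were higher (median 1.35). The astrocyte gene alrm, at 29.5 CPM, was 29.0-fold higher (18.4 to 48.4) and the glia list had a median of 0.61. Most of the lower genes with the largest folds encode larval cuticle proteins, such as Vajk3 (1797-fold, 912 to 4162) and Lcp4 (606-fold, 447 to 845), and others were the protease gene CtsK2 (640-fold, 294 to 1746) and the muscle gene TpnC25D (323-fold, 176 to 675). Muscle markers were lower in 7 of 10 (median -3.14), for example Act57B at 77.6 against 1474 CPM. Hemocyte markers, from circulating blood cells, were lower in 9 of 11 (median -1.96), with PPO2 7.58-fold (7.26 to 7.93) and Hml 5.42-fold lower. The matrix list held 4 lower genes of 14, among them Ndg (6.53-fold, 4.42 to 9.95), vkg (4.19-fold, 3.95 to 4.45) and Col4a1 (3.72-fold). Antimicrobial peptide genes were lower in 10 of 14 (median -1.71), such as CecC (139-fold, 54.1 to 513). Heat shock genes were higher in 7 of 13 (median 1.00, or 0.34 with the member at 0 counts set to its bound), although near-identical Hsp70 copies share reads and are uncertain one by one. Also outside their bands were the medians of the matrix (-0.31), cell death (0.42), glycolysis (-0.42) and neuron (0.36) lists and of the Turandot list of 1 gene (3.01). A set chosen after seeing the data held 157 genes that were at least 4-fold higher in the control than in each other eye-antennal library. By this definition all of them are called lower in every comparison over control. Without them, 171 genes were lower in RasV12.

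BskDN against control addressed the block of JNK without a tumour genotype, at labelled ages of 11 and 5 days, while the other 2 libraries with BskDN are labelled 6 days. The JNK and AP-1 list was near control (median -0.02), and 3 of its 15 genes were at least 2-fold lower. The oxidase maturation gene mol was 7.19-fold (5.42 to 9.69), Ilp8 2.64-fold (1.42 to 5.15) and the factor gene Atf3 2.36-fold lower. Genes of the response to the moulting hormone ecdysone were more often higher: 7 of 17 were at least 2-fold higher and 2 lower (median 0.46), with Eip93F 4.68-fold (3.93 to 5.60), ImpL1 3.32-fold and ImpE2 3.05-fold higher (3.01 to 3.09), and ftz-f1 2.84-fold lower. Lactate dehydrogenase (Ldh) was 6.06-fold lower (5.43 to 6.79) and the glycolysis median was -0.47.

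In total 69 genes were higher in BskDN and 329 lower. Fat body genes led in level, with Fbp1 at 3641 CPM (38.4-fold, 36.6 to 40.3) and the storage protein gene Lsp2 13.2-fold higher (12.5 to 13.9), and 6 of 9 fat body markers were at least 2-fold higher and 2 lower (median 2.77). Drsl5, an antimicrobial peptide relative, was 161-fold (73.6 to 439) and Cc2d2a, a ciliary gene, 85.7-fold higher (48.8 to 166). The antimicrobial peptide list itself had 9 of 14 genes lower and none higher (median -1.48), with DptA 51.5-fold lower (26.9 to 113). 5 of 9 neuron markers were higher (median 1.20), with VGlut 6.12-fold higher (3.11 to 13.4). The photoreceptor list had 2 of 21 genes higher (median 0.55), with pros, a neural and cone cell factor gene, 3.78-fold higher (3.26 to 4.40). The odorant-binding protein gene Obp56a was 223-fold and the neuropeptide-like gene Nplp4 477-fold lower (315 to 762). Muscle markers had a median of -3.78, with Mlc2 69.0-fold lower (62.2 to 76.9). The male-biased dosage compensation RNAs lncRNA:roX1 (X:3857230-3862697) and lncRNA:roX2 (X:11579065-11580432) were 4.17-fold (3.98 to 4.37) and 10.3-fold lower (7.99 to 13.5), and the dosage compensation list had a median of -0.44. The Ras/MAPK median was 0.56 with no gene past 2-fold. The Hippo median was 0.28, the heat shock median 0.91 and the cell cycle median -0.20. Also outside their bands were the medians of cell death genes (0.40), hemocyte markers (-0.22), glia markers (0.45), trachea and salivary gland markers (-1.24) and the Turandot gene (3.42). Age, transgene and roX levels differ together here, so that a difference in the sex of the larvae cannot be told apart from them either. Without the control-only genes, 172 genes were lower.

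The scrib BskDN library against control addressed scrib loss with JNK blocked. In the JNK and AP-1 list Ets21C was 8.22-fold (5.76 to 12.1), the growth factor gene Pvf1 2.84-fold, the JNK phosphatase gene puc 2.495-fold (2.31 to 2.70) and the matrix metalloprotease gene Mmp1 2.42-fold higher (2.27 to 2.58), so that 4 of its 15 genes were at least 2-fold higher and 1 lower (median 0.66). The receptor gene et was 2.71-fold and the cytokine gene upd3 2.497-fold higher (1.43 to 4.54), the 2 members of 10 in the JAK/STAT list past 2-fold (median 0.53). The Hippo list, with kibra 2.51-fold and expanded (ex) 2.04-fold higher (1.98 to 2.11), had 2 of 18 genes past 2-fold and a median of 0.47.

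Here 312 genes were higher and 316 lower. Neural genes were prominent among the higher ones: all 9 neuron markers were at least 2-fold higher (median 2.74), among them the glutamate transporter gene VGlut (57.7-fold, 31.2 to 121) and Gad1 (55.2-fold, 26.5 to 138), and in the photoreceptor list pros was 25.5-fold (22.3 to 29.3) and fne 20.1-fold higher (16.2 to 25.2). Heat shock genes were higher in 10 of 13 (median 2.47), with Hsp68 23.8-fold higher (22.4 to 25.4). Glue genes were higher too, with Sgs1 80.1-fold (51.1 to 133) and Sgs3 36.1-fold higher. In the trachea and salivary gland list 7 genes were at least 2-fold higher and 1 was lower (median 2.56). Among the lower genes were Obp56a (285-fold, 216 to 386), Vajk3 (247-fold, 192 to 323) and 9 of 11 hemocyte markers (median -1.20). Muscle markers had a median of -2.52 and antimicrobial peptide genes one of -3.39, or -3.09 with members at 0 at their bound. Also outside their bands were the medians of stress transcription factors (0.45), photoreceptor genes (0.34), the antenna list (0.49), the cell cycle (-0.16), ecdysone response genes (0.42), glycolysis (-0.53) and fat body markers (0.94). Without the 271 genes that were at least 4-fold higher in scrib BskDN than in BskDN, at 5 CPM or more, a set chosen after seeing the data, 133 genes were higher, and without the control-only genes 159 were lower.

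The early tumour against control addressed which genes differ in the RasV12 scrib genotype. Ilp8 (FBgn0036690, 3L:17029812-17032080), which delays metamorphosis, was 174-fold higher (127 to 245), at 364 against 2.09 CPM. Ets21C (FBgn0005660, 2L:544925-552923) was 84.2-fold higher (60.2 to 122). The 3 cytokine genes of the JAK/STAT pathway were all higher: upd2 (FBgn0030904, X:18240654-18243284) 65.5-fold (40.7 to 113), upd3 (X:18277233-18284596) 44.9-fold (28.3 to 76.1) and upd1 (X:18305354-18309291) 16.1-fold (12.9 to 20.3). Mmp1 (FBgn0035049, 2R:24671294-24688184) was 19.1-fold higher (18.0 to 20.2), at 1309 against 68.6 CPM.

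By list, 9 of 15 JNK and AP-1 genes were at least 2-fold higher (median 1.23), with Pvf1 4.80-fold higher (4.18 to 5.54). The JNK phosphatase gene puc, named here after its values were seen, was 3.29-fold higher. In the JAK/STAT list 5 of 10 genes were higher (median 1.60), including the feedback gene Socs36E (5.16-fold, 4.83 to 5.50) and the factor gene chinmo (6.78-fold, 6.38 to 7.22). The Hippo and Yorkie list had 5 of 18 genes past 2-fold and a median of 0.31 against a band that ended at 0.25, with dally 2.39-fold, kibra 2.38-fold and fj 2.29-fold higher. Among the stress transcription factors 5 of 16 were higher (median 0.70), with the nuclear receptor gene ftz-f1 3.26-fold and Dif 2.90-fold higher (2.54 to 3.32). The other higher members of this list also stand in the JNK and AP-1 or JAK/STAT list, so that it is not separate evidence. The Ras/MAPK list had sty 2.80-fold and Mkp3 2.75-fold higher (2.55 to 2.97) and the ligand-processing gene ru 3.35-fold lower (2.93 to 3.84), with a median of 0.36. Of the cell death genes 4 of 11 were higher (median 0.92), among them grim (3.41-fold, 2.07 to 5.90). The polarity and adhesion list had a median of 0.37 above its band with no gene past 2-fold. The cell cycle list (median 0.13), the matrix list (-0.08), the wing patterning list (-0.09) and the neuron list (0.24) were within their bands. Outside the lists, the mucin gene Muc11A was 435-fold (77.8 to 17230) and the protease gene CtsL2 398-fold higher (71.1 to 15759), each with 1 count in control, the matrix gene Tig reached 4050 CPM (21.0-fold, 20.3 to 21.7) and the tyrosine decarboxylase gene Tdc1 was 21.9-fold higher (18.4 to 26.3).

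Genes of the photoreceptor and antenna lists were more often lower than higher in the early tumour. The proneural gene ato was 4.79-fold (4.17 to 5.53), sens 3.92-fold (2.99 to 5.18) and gl 2.93-fold lower, in a photoreceptor list with 6 of 21 genes lower and 1, pros, higher (median -0.73). In the antenna list 4 of 10 were lower (median -0.86), among them Antp, at 0.476 against 11.98 CPM, and ss, 2.80-fold lower. Ecdysone response genes were lower in 7 of 17 and higher in 3 (median -0.87). ImpE2 (FBgn0001254, 3L:3510974-3512681) was 164-fold (145 to 187), Hr3 (2R:10203995-10237348) 148-fold (86.2 to 278) and ImpL1 29.0-fold lower, while Cyp18a1, which inactivates ecdysone, was 4.72-fold higher (3.98 to 5.64). Heat shock genes were lower in 8 of 13 and higher in 2 (median -1.37), with Hsp23 13.9-fold lower (13.5 to 14.5).

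The calls were 101 genes higher and 437 lower. Of the lower genes 157 were at least 4-fold higher in the control than in each other eye-antennal library, and 280 were lower without them. Most of the largest folds were of cuticle genes, such as Lcp4 (1851-fold, 1103 to 3387). Muscle markers were lower in 6 of 10 (median -3.10), fat body markers in 6 of 9, 2 being higher (-3.001), trachea and salivary gland genes in 8 of 11 (-2.16), hemocyte markers in 6 of 11 (-1.11) and antimicrobial peptide genes in 10 of 14 (-3.38, or -2.75 with members at 0 at their bound). The glycolysis median was -0.44, although Ldh was 3.47-fold higher. 3 of 8 glia markers were higher (median 0.56), with moody 3.96-fold higher (3.60 to 4.36).

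**Figure D2:**
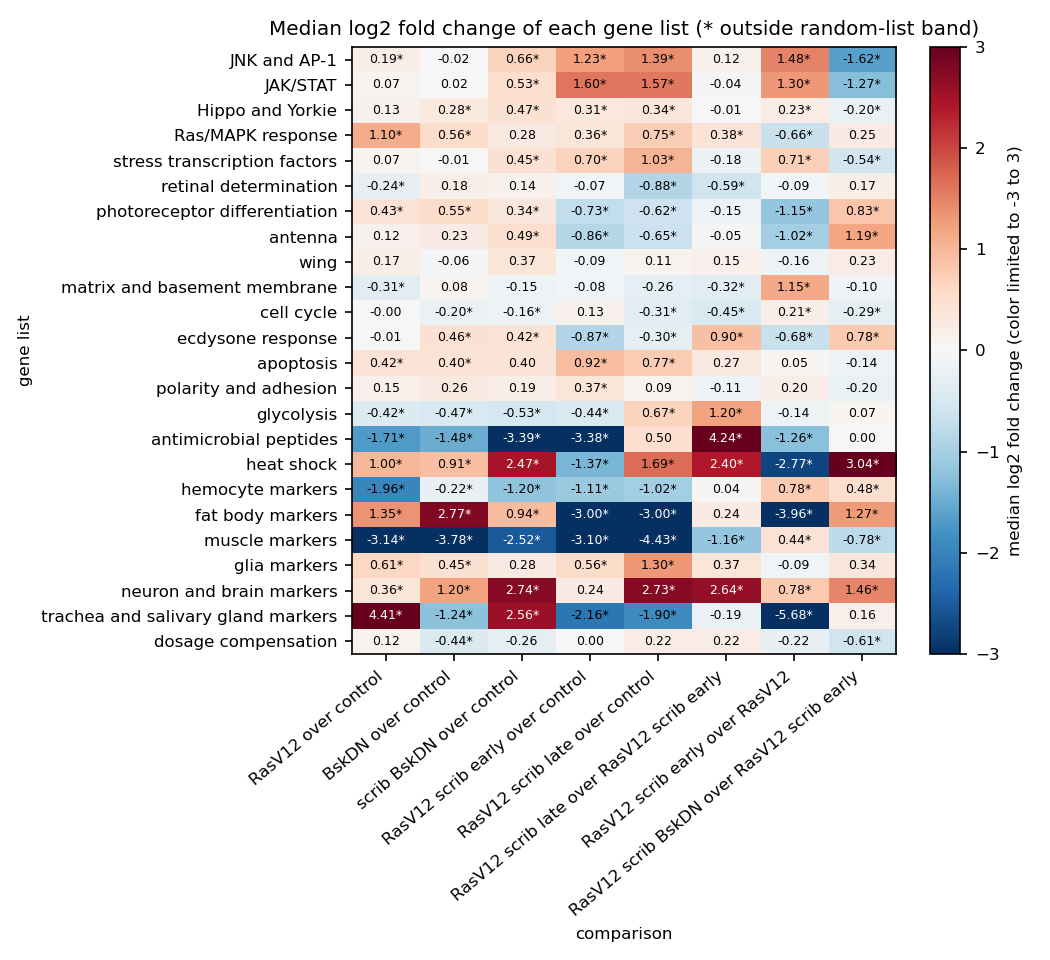
Median log2 fold of 24 gene lists (vertical axis) in the 8 comparisons (horizontal axis), printed in each cell, where * marks a median outside the band of matched random lists and the color is limited to -3 to 3. The JNK and AP-1 median was 1.23 in the early tumour over control and -1.62 in RasV12 scrib BskDN over the early tumour.

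The late tumour against control addressed the same genotype after 11 days. The signals that were high in the early tumour were high here too. Ilp8 was 270-fold (198 to 380), Ets21C 112-fold (79.8 to 161), upd2 60.6-fold (37.7 to 104), upd3 57.5-fold (36.2 to 97.4) and Mmp1 18.7-fold higher (17.7 to 19.8). 10 of 15 JNK and AP-1 genes were at least 2-fold higher (median 1.39), 5 of 10 JAK/STAT genes (1.57), 5 of 18 Hippo and Yorkie genes (0.34) and 8 of 16 stress transcription factors (1.03). The Ras/MAPK median was 0.75, with sty 5.04-fold higher (4.79 to 5.31). The border cell factor gene slbo was 33.4-fold higher (5.63 to 1357) but had 1 count in control. Retinal determination genes were lower in 5 of 13 (median -0.88), with dan 4.14-fold (3.70 to 4.64), dac 3.84-fold (3.64 to 4.05), eya 2.99-fold and so 2.91-fold lower. The photoreceptor list had 9 lower and 3 higher genes (median -0.62), with ato 13.4-fold (10.7 to 16.9) and gl 5.42-fold lower (4.96 to 5.92). The antenna list median was -0.65.

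With 596 genes higher and 395 lower, this comparison had the most calls of the 8. Ldh was 18.8-fold higher (18.0 to 19.6), at 2229 CPM, and the glycolysis median was 0.67. Neuron markers were higher in 8 of 9 (median 2.73), with VGlut 76.1-fold (41.2 to 159) and Gad1 53.2-fold higher (25.6 to 133), and glia markers in 4 of 8 (median 1.30), with Eaat1 13.5-fold higher (10.3 to 17.9). Mucin and peritrophin genes were among the largest folds, with Peritrophin-15a 708-fold higher (344 to 1763). The heat shock median was 1.69, the cell cycle median -0.31 and the muscle median -4.43, while the antimicrobial peptide median of 0.50 was within its band. ImpE2 was 16.3-fold and Hr3 28.2-fold lower (22.0 to 36.7). Also outside their bands were the medians of ecdysone response genes (-0.30), cell death genes (0.77), hemocyte markers (-1.02), fat body markers (-3.001) and trachea and salivary gland markers (-1.90). Without the control-only genes 238 were lower.

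The late against the early tumour addressed what differs with age in 1 genotype. The JNK, JAK/STAT and Hippo lists were close to each other in the 2 libraries, while glycolytic, neural and immune genes differed. Named after their values were seen, Mmp1 had a fold of 0.980 (0.963 to 0.996) and Ilp8 one of 1.55 (1.51 to 1.60). The medians of the JNK and AP-1 (0.12), JAK/STAT (-0.04) and Hippo and Yorkie (-0.01) lists were within their bands. The Ras/MAPK median was 0.38, above its band of -0.28 to 0.12, with sty 1.80-fold higher (1.75 to 1.86) and ru 2.63-fold lower (2.10 to 3.33), and Ras85D was at 1181 against 655 CPM. Glycolytic genes were higher in the late tumour in 7 of 12 (median 1.20), with Ldh 5.42-fold (5.30 to 5.55), phosphofructokinase (Pfk) 3.61-fold and aldolase (Ald1) 3.01-fold higher. Retinal determination genes had a median of -0.59, with so and dac each 2.11-fold lower, and the cell cycle list one of -0.45 with none of 24 genes past 2-fold.

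The calls were 526 genes higher and 14 lower. Neuron markers were higher in 8 of 9 (median 2.64), with Gad1 17.5-fold (11.6 to 27.6) and VGlut 16.8-fold higher. The photoreceptor list, with fne 22.5-fold higher, had 4 genes higher and 3 lower and a median of -0.15 within its band. Antimicrobial peptide genes were higher in 11 of 14 (median 4.24, or 3.73 at the bound), and DptA, with 0 counts in the early tumour, was at least 143-fold higher. The stress gene TotA, the only considered member of the Turandot list, was at least 55.2-fold higher for the same reason. Heat shock genes were higher in 11 of 13 (median 2.40), with Hsp68 18.4-fold and Hsp26 15.7-fold higher. The ecdysone list had 8 of 17 genes higher (median 0.90), with Eip93F 11.8-fold and ImpE2 10.1-fold higher. Peritrophin-15b, with 0 counts in the early tumour, was at least 985-fold higher at 141 CPM. The 4 lower genes that the naming rule takes were the mucin gene Muc11A (11.7-fold, 8.48 to 16.6) and the muscle genes up (6.49-fold), Mlc1 (5.58-fold, 4.58 to 6.85) and Tm2 (4.62-fold, 3.92 to 5.46). The medians of matrix genes (-0.32), muscle markers (-1.16) and the Turandot gene (6.29) were outside their bands too. Without the 271 genes defined by scrib BskDN, 403 genes were higher and 9 lower.

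The early tumour against RasV12 addressed what scrib loss adds to active Ras. JNK and JAK/STAT genes were higher in the tumour. The cytokine upd2 was 80.2-fold (48.5 to 144), Ilp8 21.6-fold (19.4 to 24.2), upd3 19.9-fold, Ets21C 19.1-fold (16.3 to 22.5), Mmp1 12.9-fold (12.3 to 13.5) and upd1 11.8-fold higher, and 10 of 15 JNK and AP-1 genes (median 1.48) and 5 of 10 JAK/STAT genes (1.30) were past 2-fold. The factor gene chinmo was 7.14-fold (6.72 to 7.59) and Pvf1 8.58-fold higher (7.22 to 10.3). Matrix genes were higher in 8 of 14 (median 1.15), with vkg 3.44-fold (3.24 to 3.65) and Col4a1 3.33-fold higher (3.18 to 3.50). Hemocyte markers were at least 2-fold higher in 4 of 11 (median 0.78), with Sr-CI 4.97-fold higher (4.38 to 5.65). Both lists were low in RasV12, with medians over control of -0.31 and -1.96. In the early tumour over control the matrix median was -0.08, within its band, and the hemocyte median -1.11, so that neither list was raised over control. In the Ras/MAPK list ru was 7.61-fold (6.72 to 8.64), edl 2.51-fold (2.23 to 2.83) and kek1 1.94-fold lower (median -0.66).

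Photoreceptor genes were lower in 11 of 21 (median -1.15), with svp 3.23-fold (2.84 to 3.69) and sens 3.23-fold lower (2.46 to 4.30), and genes of the antenna list in 5 of 10 (median -1.02), with al 6.60-fold and bab2 3.24-fold lower (2.96 to 3.55). The ecdysone list had 8 genes lower and 3 higher (median -0.68), with ImpE2 176-fold (155 to 200) and Hr3 50.0-fold lower (29.0 to 94.4). The calls were 145 higher and 208 lower. Glue and fat body genes led the lower ones, with Sgs7 680-fold (397 to 1277) and Fbp1 399-fold lower and medians of -5.68 for the trachea and salivary gland list and -3.96 for fat body markers, and the heat shock median was -2.77. The Hippo median was 0.23, that of stress transcription factors 0.71 and that of the cell cycle 0.21. The medians of muscle markers (0.44) and the Turandot gene (-6.54) were outside their bands too. Prosalpha1, 26.6-fold higher, has a near-identical copy and is uncertain. The antimicrobial peptide median of -1.26 came to -0.80, within its band, with members at 0 at their bound.

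RasV12 scrib BskDN against the early tumour addressed which tumour genes depend on JNK. The signals that were high in the tumour were much lower with JNK blocked. Ilp8 was 34.4-fold (30.03 to 39.5), upd2 25.2-fold (18.9 to 34.2), Ets21C 24.8-fold (20.8 to 29.8), upd3 18.3-fold (13.7 to 24.9), Mmp1 10.5-fold (10.1 to 10.9), upd1 9.27-fold and chinmo 8.94-fold lower (8.37 to 9.57). 9 of 15 JNK and AP-1 genes were at least 2-fold lower (median -1.62), with mol 8.06-fold lower, and 5 of 10 JAK/STAT genes were lower and 1, zfh1, higher (median -1.27). Among stress transcription factors 6 of 16 were lower (median -0.54), with ftz-f1 6.44-fold and Dif 3.36-fold lower (2.94 to 3.86). In the Hippo and Yorkie list 1 of 18, fj, was lower, by 2.75-fold (median -0.20), and the Ras/MAPK median of 0.25 was within its band. Ras85D itself was 1.54-fold lower (1.497 to 1.58).

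Photoreceptor genes were higher in 7 of 21 (median 0.83), with fne 9.21-fold (7.74 to 11.0) and pros 4.71-fold higher (4.34 to 5.11). Both fne and pros were also higher in scrib BskDN than in control, as were all 9 neuron markers. Here 7 of 9 neuron markers were at least 2-fold higher, so that fne and pros do not tell retinal from other neural RNA. Genes of the antenna list were higher in 5 of 10 (median 1.19), with Antp 10.1-fold (5.25 to 21.6), al 4.77-fold and bab2 4.46-fold higher (4.09 to 4.87). The ecdysone list had 8 genes higher and 2 lower (median 0.78), with Hr3 384-fold (225 to 722) and ImpE2 184-fold higher (162 to 209). The calls were 241 higher and 156 lower. The medians of heat shock genes (3.04), fat body markers (1.27), neuron markers (1.46), hemocyte markers (0.48) and the Turandot gene (3.93) were above their bands, those of muscle markers (-0.78) and the cell cycle (-0.29) were below, and Fbp1 was 178-fold higher. With its 0 counts in the early tumour at the bound, the Turandot value came to 3.35, within its band. The roX RNAs were lower here as well, with a dosage compensation median of -0.61, and Ldh was 7.84-fold lower (7.36 to 8.36).

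**Figure D3:**
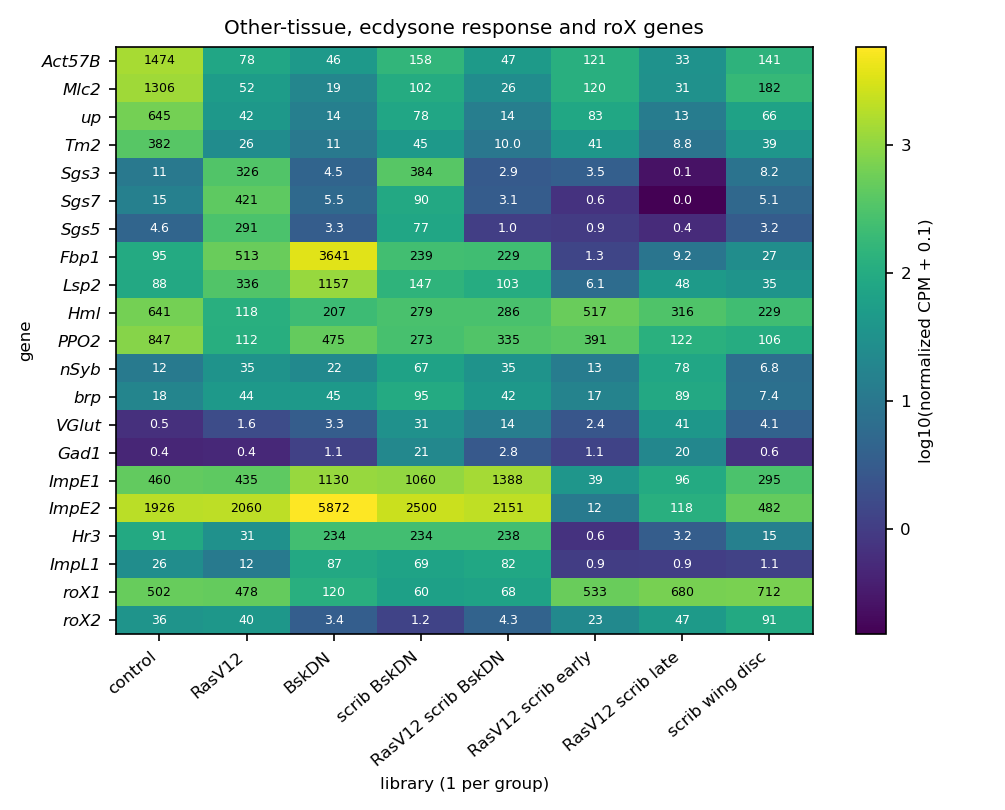
Normalized CPM of 21 genes of other tissues, of the ecdysone response and of dosage compensation (vertical axis) in the 8 libraries (horizontal axis), with the CPM printed in each cell and the color on a log10 scale. Act57B was at 1474 CPM in control and at most 158 CPM in the other 7 libraries, and Fbp1 reached 3641 CPM in BskDN.

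Pairs of comparisons with no library in common were set side by side, so that no shared control could link them. Of the 101 genes higher in the early tumour than in control, 90 were at least 2-fold higher in the late tumour than in RasV12, and 92 were at least 2-fold lower in RasV12 scrib BskDN than in the late tumour, with none higher and a median of -2.73. By calls, 76 genes were higher in both of the former pair, where independent lists would share 5.21, and 67 were higher and then lower in the latter pair against 3.74. In the former pair 82 genes were lower in both (8.15), none was higher and then lower (1.88) and 18 were lower and then higher (22.5). In the latter pair 88 were lower and then higher (6.97), none was higher in both (1.61) and 28 were lower in both (16.2). Across 7628 genes, which are not independent replicates, the Pearson correlations of these pairs were 0.37 and -0.30 and the Spearman correlations 0.48 and -0.55. BskDN over control and RasV12 scrib BskDN over the early tumour shared 19 higher genes (1.66 for independent lists) and 44 lower genes (5.12). A further 1 was higher and then lower (1.07) and 5 lower and then higher (7.91), with correlations of 0.33 and 0.35. Both contrasts also had lower lncRNA:roX1 (4.17- and 7.88-fold) and lncRNA:roX2 (10.3- and 5.34-fold). Their ecdysone, fat body, neuron and muscle medians went the same way, while those of Hippo and hemocyte genes did not. Sex, stage or dissected tissue can thus link this pair, and BskDN cannot be told apart from them. RasV12 over control and RasV12 scrib BskDN over scrib BskDN shared 6 higher (0.983) and 50 lower genes (5.89), but 16 genes were higher in the former and lower in the latter (1.67) and 10 the other way (3.47), and their correlations were 0.09 and -0.02. Of the 93 genes higher in RasV12, 13 were at least 2-fold higher in the latter contrast and 31 at least 2-fold lower. The early tumour over RasV12 and scrib BskDN over BskDN, the 2 contrasts of scrib loss, shared 12 higher (3.92) and 28 lower genes (2.72), while 24 were lower in the former and higher in the latter (5.62) and 2 the other way (1.89), with correlations of 0.04 and 0.22.

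**Figure D4:**
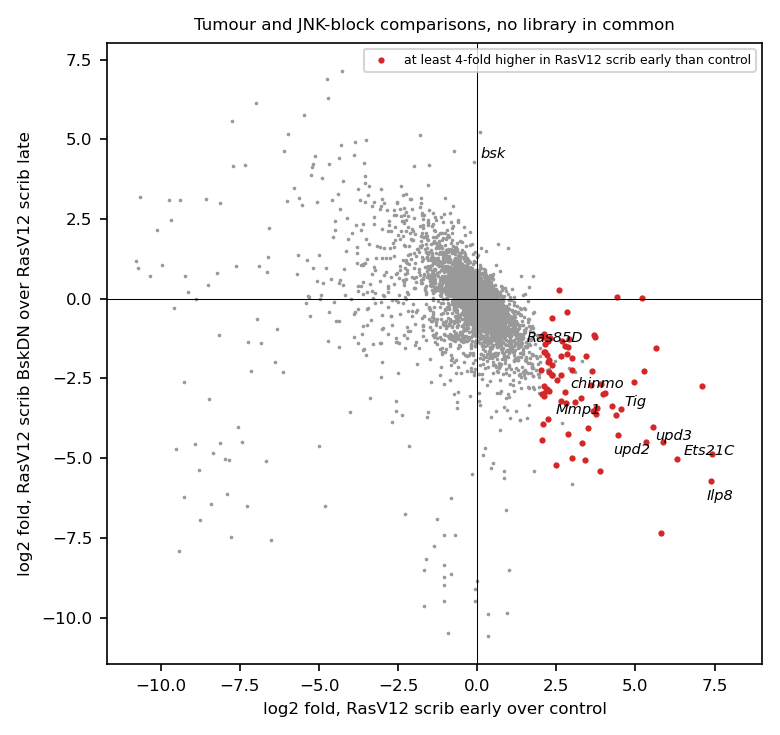
Each point is a gene with a mean of at least 5 CPM, with the log2 fold of the early tumour over control on the horizontal axis and that of RasV12 scrib BskDN over the late tumour on the vertical axis, and red points were at least 4-fold higher in the early tumour. Of the 80 red genes 77 lie below 0 on the vertical axis.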

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

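In this part, the tests of the loss of tumour genes under BskDN were chosen only after that result was seen. The other tests were set before their values were computed, except the count with at least 5 CPM in scrib BskDN, which was added later.

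The first pattern is the set of 437 genes lower in the early tumour than in control. RNA from larval tissue present in the control sample alone is a candidate source of part of it, since 157 of them (35.93%) were at least 4-fold higher in the control than in each of the 5 other eye-antennal libraries, 23 of the 30 cuticle-named genes in the pattern, a group formed after seeing the data, among them. A difference in stage may account for another part, as 148 genes (33.87%) were also at least 4-fold lower in the early tumour than in RasV12, a library of 5-day larvae with higher ecdysone genes. The groups shared 14 genes, and 146 of the 437 were in neither, so that neither explanation was shown to cover the pattern. The genotype itself stays open, and with 1 control library these cannot be told apart gene by gene.

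The second pattern is the excess of higher genes in the late over the early tumour, 526 against 14. For an age of 11 days as the whole cause, 24 of the 526 (4.56%) were at least 4-fold higher in BskDN at 11 days than in RasV12 at 5 days. That share lies under the 25% set as the bound against age. It cannot decide the question, because these libraries also differ in transgene and roX levels, and neither is of the tumour genotype. The age on the BskDN label, where the other libraries with BskDN have 6 days, would have to be right too. Nervous tissue dissected with the discs may account for part, since 181 (34.41%) were also at least 4-fold higher in scrib BskDN than in BskDN at any level, or 123 (23.4%, under the 25% set as the bound against it as the whole cause) among genes with at least 5 CPM in scrib BskDN, and 8 of 9 neuron markers lay within 2-fold between the late tumour and scrib BskDN (median log2 difference -0.05, with VGlut at 40.9 and 31.0 CPM). Outside the wider of these sets were 345 genes, among them the glycolytic gene Ldh and 8 of the 10 higher genes in a group of 27 with names of mucins, peritrophins and digestive or chitin proteins, which was formed after seeing the data, so that a further tissue stays open. Whether the neural RNA comes from attached brain or from cells of the discs cannot be told apart, because no library of brain was made.

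The third pattern is the loss, under BskDN, of the 101 genes that were higher in the early tumour. A smaller share of transgene-expressing tissue as the whole cause was read from Ras85D. RasV12 scrib BskDN kept a median of 6.74% of the genes' excess over control (bootstrap over genes, which are not independent, 3.28 to 9.74%). It kept 42.99% of the excess of Ras85D, a share that 14 of the 101 exceeded. Measured on the late tumour, which was not used to choose the genes, the shares were closer, 5.76% (2.497 to 9.094%) for the genes and 18.6% for Ras85D. These values argue against a loss in proportion to Ras85D RNA. They cannot decide the share of tissue, because Ras85D was not in step with the tumour signals. It was at 655 CPM in the early and 1181 CPM in the late tumour, while the JNK and AP-1 median between them was 0.12. Sex and stage both stay open, since 0 of the 2 tumour libraries without BskDN had lncRNA:roX2 within 2-fold of the BskDN libraries, and 0 of the 5 other eye-antennal libraries had the ecdysone gene ImpE1 within 2-fold of the tumours. A need for JNK activity, the change the design names, is consistent with these values and remains a hypothesis from single libraries.

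Contrasts named for the same genetic change in 2 backgrounds were compared by list median in 72 cases (24 lists and 3 contrasts). In 13 of them both medians lay outside their bands of random lists, on opposite sides. Further pairs had opposite signs with a median within its band and are not counted. The differences were not tested. The contrasts do not isolate the change, since labelled ages differ too, for example 11 and 5 days in BskDN over control and 6 and 11 days in scrib BskDN over BskDN. Many of the lists are markers of other tissues, and glue genes were high in both RasV12 and scrib BskDN, so that dissected tissue cannot be told apart from the change. For RasV12, the median over control and that of RasV12 scrib BskDN over scrib BskDN differed by 0.616 for JNK and AP-1 (0.191 and -0.425), 0.787 for photoreceptor genes (0.434 and -0.353), 3.167 for heat shock genes (1.003 and -2.164), -2.946 for hemocyte markers (-1.96 and 0.987), 2.041 for fat body markers (1.354 and -0.688), 1.515 for neuron markers (0.358 and -1.157) and 8.531 for trachea and salivary gland markers (4.409 and -4.122). For BskDN, the median over control and that of RasV12 scrib BskDN over the early tumour differed by 0.483 for Hippo and Yorkie (0.285 and -0.198) and -0.693 for hemocyte markers (-0.217 and 0.477). For scrib loss, the median of the early tumour over RasV12 and that of scrib BskDN over BskDN differed by 1.5 for matrix genes (1.146 and -0.354), -4.359 for heat shock genes (-2.765 and 1.594), 1.849 for hemocyte markers (0.78 and -1.07) and -9.422 for trachea and salivary gland markers (-5.685 and 3.737).

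The tally of reads aligned to several places, which no comparison uses, was above the 21.1% of control in RasV12 scrib BskDN (23.098%) and in the late tumour (27.82%).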

How the results depend on the processing

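The 2 settings that leave out gene sets were chosen only after the results were seen. No fold of a named gene turned its sign, while a few list medians close to 0 did. The balance of calls in scrib BskDN over control did turn: 49.7% were higher as reported, and 52.8% with total counts, 52.0% with upper-quartile scaling, 56.8% at 1 CPM and 58.4% with no level filter, against 45.5 to 49.6% under the other settings planned. Of 194 counts under other settings, 126 were within 1.5 times the reported one, and no scaling, prior count or removal of the 20 top genes moved a count further. List medians stayed within an interval from resampling the members of the list in 997 of 1040 cases. Of the 43 that moved, 40 were the Turandot list. Its 1 gene gives an interval of no width, so that any change counts as moved. Folds of named genes stayed within their interval for counting error in 2567 cases and moved in 33. No paired analysis was possible because each group had 1 library. A prior count of 0.5 gave correlations of 0.307, 0.346 and -0.263 in place of 0.330, 0.368 and -0.300. The other settings let in genes of smaller fold or lower level, or leave genes out, by construction. Depth limits genes near 3 counts, where a fold can be a bound alone.

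With a 2-fold threshold the counts higher and lower were 289 and 562 for RasV12 over control, 297 and 500 for BskDN, 693 and 782 for scrib BskDN, 334 and 800 for the early tumour, and 1076 and 724 for the late tumour. They were 948 and 115 for the late over the early tumour, 402 and 626 for the early tumour over RasV12, and 687 and 421 for RasV12 scrib BskDN over the early tumour. The share of higher genes went from 17.3 to 37.3% for BskDN, from 22.1 to 34.0% for RasV12 and from 18.8 to 29.4% for the early tumour.

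With a level filter of 1 CPM they were 161 and 513 for RasV12, 142 and 541 for BskDN, 174 and 691 for the early tumour, 834 and 43 for the late over the early tumour, 228 and 350 for the early tumour over RasV12, and 408 and 243 for RasV12 scrib BskDN over the early tumour. The higher genes were 616 for scrib BskDN and 897 for the late tumour over control.

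With no level filter they were 225 and 591 for RasV12, 199 and 626 for BskDN, 761 and 542 for scrib BskDN, 237 and 781 for the early tumour, 1053 and 646 for the late tumour, 999 and 61 for the late over the early tumour, 289 and 460 for the early tumour over RasV12, and 484 and 285 for RasV12 scrib BskDN over the early tumour.

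Without the 157 genes higher in the control alone, the lower genes were 171 for RasV12, 172 for BskDN, 159 for scrib BskDN, 280 for the early tumour and 238 for the late tumour. Each of these counts falls by 157 by definition, so that the drop is no check of the calls. Without the 271 genes higher in scrib BskDN than in BskDN, at 5 CPM or more, 133 were higher in scrib BskDN than control, and in the late over the early tumour 403 were higher and 9 lower.

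Shared calls at 2-fold, at 1 CPM and with no level filter were 135, 91 and 111 genes lower in both contrasts of RasV12, 174, 48 and 68 higher in both of BskDN, 236, 124 and 155 higher in the early tumour over control and the late tumour over RasV12, 239, 104 and 124 higher in the early tumour and lower in RasV12 scrib BskDN than in the late tumour, and 80, 32 and 54 higher in both contrasts of scrib loss.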

Other observations

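In this part, the test of sex in the BskDN libraries was chosen only after the roX values were seen. The library labelled scrib wing discs, which by its genotype carries scrib mutant tissue throughout and no RasV12, had high levels of several tumour signal genes. Mmp1 was at 1118 CPM, Ilp8 at 110 CPM, Ets21C at 64.2 CPM, puc at 208 CPM, cher at 1835 CPM, scaf at 701 CPM, and upd1, upd2 and upd3 at 51.5, 45.3 and 25.1 CPM. The control eye-antennal library had 68.6 CPM of Mmp1 and 2.09 CPM of Ilp8, but the library labelled scrib wing discs is by that label of another tissue, although no gene of the wing list was at least 2-fold higher there. These genes, some of them outside the naming rule, were chosen after their values were seen.

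The 5 genes of the dosage compensation list, RNAs and proteins that differ between the sexes, each split the libraries by transgene. The level of lncRNA:roX1 was 60.1 to 120 CPM in the 3 BskDN libraries and 478 to 711 CPM in the other 5, and that of lncRNA:roX2 was 1.18 to 4.31 CPM against 23.0 to 91.4 CPM. The msl-2 gene was also lower, at 39.8 to 50.5 CPM against 60.6 to 70.6 CPM. Higher in the BskDN libraries were Sxl, at 387 to 559 CPM against 259 to 320.5 CPM, and dsx, at 61.4 to 86.3 CPM against 13.0 to 57.9 CPM. No p-value is given, since the split was chosen after these values were seen. Larvae that were all female in these crosses are a candidate explanation, because the labels place the BskDN transgene on an X chromosome beside one that carries the recombinase, and roX RNA is made mainly in males. Of all genes considered, 1, lncRNA:roX2, was at least 4-fold lower in each BskDN library than in each other library, while lncRNA:roX1 missed that threshold. As many were found in 7 of the 56 splits of the 8 libraries into 3 and 5, with 5 genes in the highest of the other splits. Chance is thus not excluded for that count, which holds only 1 of the 5 genes of the list and weighs neither for nor against all-female larvae. The difference was not limited to the roX genes. Larvae with both of these X chromosomes, as the labels give them, would be female. Each comparison of a BskDN library with a library without BskDN would then differ in sex too. No library had larvae of recorded sex, so the explanation was not checked directly.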
